A study of Mus musculus with 24 samples.

How the data were processed

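The samples were mouse embryos in culture at 37 °C. One group was exposed to 40 µM 4-hydroperoxycyclophosphamide (4CP, which per the labels is an already activated analogue of the anticancer drug cyclophosphamide) for 1 h, and the other group was left untreated. Cyclophosphamide itself has to be converted by the liver before it alkylates DNA and protein. RNA of treated and of control embryos was hybridised together, 1 in each channel, on 24 two-channel arrays. The stage of the embryos, the number pooled per RNA sample and the dyes are not given in the sources used here.

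The 24 array records fell, by their titles, into 12 slides with 2 records each, and the slides into 6 slide pairs, in which the second slide carried the channels swapped. The 2 records of a slide differ by a letter B in the title. The labels do not say whether they are 2 arrays or repeat scans of 1, and they are called arrays here. In 12 arrays the treated RNA was in channel 1, and in the other 12 in channel 2. The values came as 2 tables of 7680 probes and 12 arrays each, on 2 platforms, and each table held 3 slide pairs. In both tables the titles number the pairs from 1 to 3, and these numbers are used here as pair 1, pair 2 and pair 3 of the first or second table. The labels do not say whether a number marks a separate culture, litter or RNA extract. The p-values of single probes and genes therefore measure only the spread between slide pairs, which may be technical.

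The deposited values are log ratios of the 2 channels, judged from the values themselves, which are centred differently in each array and run from -2.60 to 7.71 in the first table and from -4.33 to 5.96 in the second. Neither the labels nor the tables state the log base. Base 10 was excluded because 7.71 exceeds the log10 of the range of a 16-bit scanner, 4.82, so the base is 2 or e, and sizes are given in log ratio units of that unstated base. A value of 0.3 is a 1.23-fold difference in base 2 and a 1.35-fold difference in base e. The numerator channel is not stated either. Effects were computed as if channel 1 were the numerator, so that a positive effect means more RNA in treated embryos; if channel 2 was the numerator, every sign turns together. For this reason the text speaks of positive and negative effects. Whether swapped slides had already been turned before deposit is also not stated. Background correction, normalization, spot intensities and quality flags are not given in the sources used here, so signal over background is unknown. The stated SDs take in only the spread between the 3 slide pairs of a table. Every value has 7 decimals and ends in 3, which leaves 6 informative decimals. No value was missing, and no filter was applied.

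Each array was centred on its median, since the deposited array medians ran from -0.305 to 1.12 in the first table and from 0.272 to 2.10 in the second. The 2 arrays of a slide were averaged. For each slide pair, the treatment effect was the difference divided by 2 between the slide with treated RNA in channel 1 and its swapped partner, in which a dye effect of a probe cancels. The dye component was their sum divided by 2. The mean treatment effect over 3 pairs was tested against 0 within each table with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had assumed log2 ratios; the test was kept, as limma's p-values do not depend on the log base.

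Probes were named through the platform annotation, updated by gene identifier. Of first-table probes, 4749 had 1 gene symbol, 227 had several and 2704 had none, and of second-table probes 4935, 275 and 2470. Only probes with 1 symbol were named, which covered 3839 and 4075 genes. Of these probes, 4712 and 4884 were found in the reference gene table by identifier. Probes of a gene were averaged for the gene lists. The 28 lists and the cell type markers among them were fixed before the data were examined, and lists with at least 5 measured genes were tested, 22 in the first table and 17 in the second. Lists of ribosomal protein, oxidative phosphorylation, proteasome, histone, translation factor, collagen and laminin, and tubulin and actin genes were set by symbol. Some of these took in other genes. The ribosomal protein list also took in ribosomal S6 kinase genes, which do not encode ribosomal proteins. The translation factor list took in Eef2kmt, Eef2k and Eif4enif1, which are not translation factors, and the proteasome list took in Psmc3ip and Psme3ip1 in the second table. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists of the table. Fry asks whether a list moves on balance 1 way, or in its mixed form in either direction, and does not compare the list with other genes. Camera does compare a list with other genes. At the preset correlation it takes genes of a list as almost independent, so its p-values do not measure the spread between slide pairs alone. Estimated correlations of the first-table lists that passed ran from -0.06 for ATF4 and unfolded protein response genes to 0.782 for glycolysis genes.

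Genes were named by a rule fixed before the data were examined: because fewer than 10 probes passed, the 10 probes per direction with the smallest p among those with the same sign in all 3 pairs; from each list the members with the smallest p; and a fixed set of stress, damage and reference genes. Cdkn1a, Trp53 and Hspa1b, which belong to that set, were not among the probes with 1 symbol.

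The steps were tested on simulated slides built from the measured dye components and the fitted spread between pairs, with 200 of 7680 probes changed. In the simulation of the first table, 66.7% of probes changed by 0.3 log units and 100% of those changed by 0.6 were called, with 4 false calls; in that of the second table all, 100%, were called at both sizes, with 7 false calls. With no effect planted, 0 probes were called in each. The simulation assumes independent noise between pairs. It planted no size under 0.3, while the 99th percentile of the measured absolute effects was 0.182 in the first table and 0.143 in the second. It therefore does not show how many probes changed by such smaller sizes would be called. Alternatives covered centring, scaling, quantile normalization, the turn of swapped slides, the use of 1 orientation alone, a fit on single arrays with a dye term, robust eBayes, other thresholds, an exact sign-flip permutation test, and leaving out each pair. Added after seeing the data were removal of the trend of the treatment effect on the dye component (loess, span 0.3), centring of runs of 240 consecutive probe numbers, and a joint fit of both tables at gene level, which joins pairs of the 2 tables by their title number although the labels do not define it.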

Results

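Gene expression was compared between cultured mouse embryos exposed to 40 µM 4CP for 1 h and untreated control embryos, to ask which transcripts respond to the activated drug this early. Each of 24 two-channel arrays held treated and control RNA, so every value is itself a treatment ratio. The values came in 2 tables of 7680 probes each, with 3 dye-swapped slide pairs per table, and n = 3 refers to these pairs throughout. Positive effects stand for more RNA in treated embryos if channel 1 was the numerator and for less if it was channel 2, which the labels leave open. They also assume that swapped slides had not been turned before deposit. If they had been, the treatment effect would be the component without the turn, called the dye component here. Effects are relative to the median probe of an array, in log ratio units. Where values were used as deposited, without centring, the median of all probes lay at -0.128 in the first table and at -0.0543 in the second, so signs of small effects hold only relative to the median probe.

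No single transcript passed the test. In the first table, 0 of 7680 probes passed an adjusted p of 0.05 with limma (lowest adjusted p = 0.997), and 180 had an unadjusted p under 0.05, where 384 would be expected by chance. Of these, 141 were positive and 39 negative. No probe of the second table passed, 0 of the same number (lowest adjusted p = 0.673), and 401 had an unadjusted p under 0.05, 91 of them positive and 310 negative. All 3 pairs shared a sign for 22.6% of probes in the first table and 24.5% in the second, where chance gives 25%. Effects were small, with a median absolute size of 0.0354 and 0.0234 log units. The fit on single arrays with a dye term also called 0 probes in each table. The count depended on the pairs used: without pair 1, 2 or 3 it was 24, 30 and 24 in the first table and 40, 58 and 0 in the second, and with values as deposited it was 33 and 1. Read without the turn of the swapped slides, as would apply if the values had been deposited as treated over control, the first table gave 219 probes past the threshold and the second 0.

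**Figure D1:**
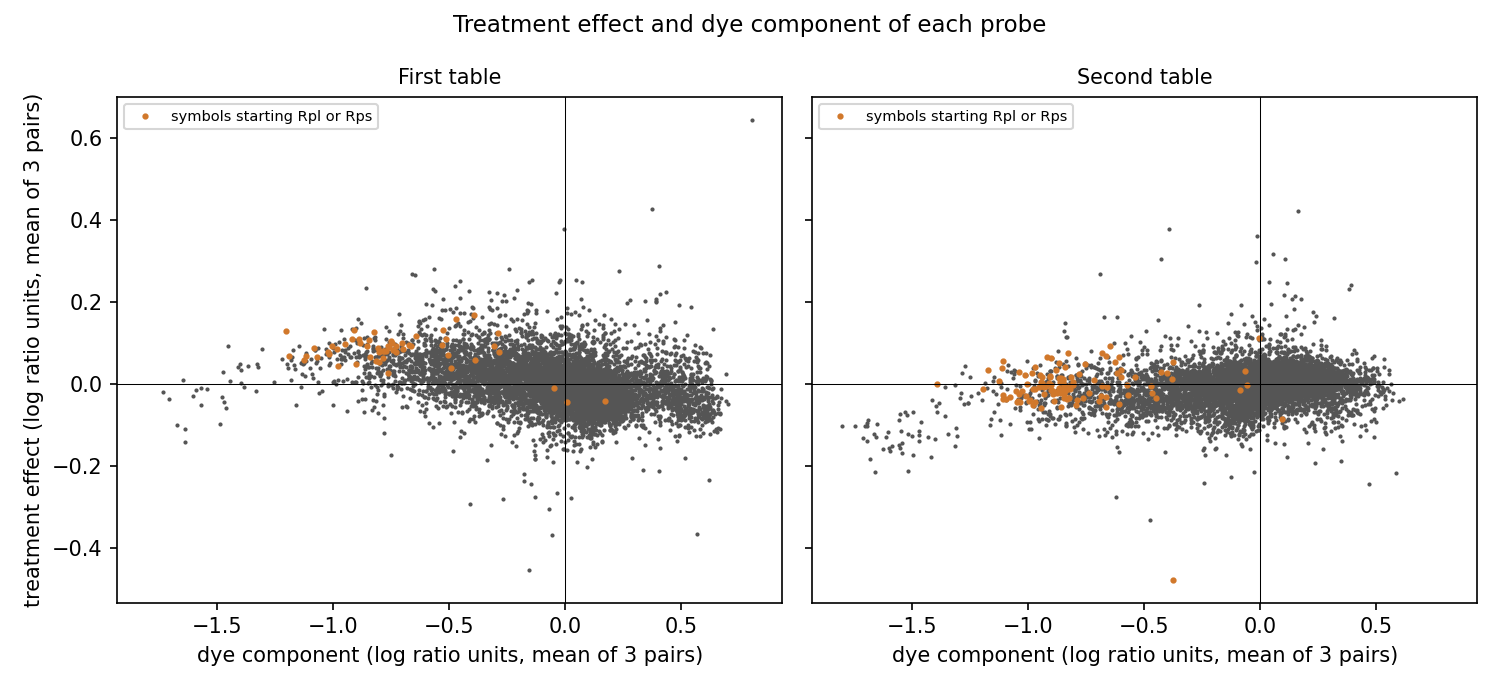
Treatment effect of each probe (vertical axis, log ratio units, mean of 3 slide pairs) against its dye component (horizontal axis, log ratio units), with first table on the left and second table on the right; orange points are probes whose symbols start with Rpl or Rps. With swapped slides turned, the dye component spreads far more widely than the treatment effect. Most of the orange points lie at negative dye components. If the values had been deposited as treated over control, the names treatment effect and dye component would change places here.

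Heat shock proteins and chaperones, which fold and protect proteins, lay mostly on the positive side in the first table with swapped slides turned. Of 25 measured genes 23 had positive effects, with a median of 0.08, and 13 were positive in all 3 pairs. The median was 0.13 in pair 1, 0.13 in pair 2 and 0.01 in pair 3. Dnajb1, a co-chaperone induced by heat shock, had an effect of 0.33 ± 0.26 (SD, n = 3), with 0.50, 0.45 and 0.03 in pairs 1, 2 and 3. Fkbp4, an HSP90 co-chaperone, had 0.26, 0.14 and 0.10, and Hspd1, the mitochondrial HSP60, had 0.18, 0.17 and 0.08, both positive in every pair. Hsp90aa1, the stress-inducible cytosolic HSP90, had 0.47, 0.26 and 0.00. Hspa8, the constitutive cytosolic HSP70, had 0.34, 0.30 and -0.22. The list passed camera at the preset correlation (adjusted p = 2.31e-10) but not with an estimated correlation (adjusted p = 0.589), nor fry (adjusted p = 0.446). None of its members passed, either over all genes or adjusted over the list alone. The list mean was -0.3145 without the turn and -0.2117 with treated RNA in channel 1 alone.

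On the second platform, 14 of 16 chaperone genes were positive, with a median of 0.04 and pair medians of 0.0357, 0.0204 and 0.0146, and the list again passed the preset test (adjusted p = 4.00e-04) but not the test with an estimated correlation (adjusted p = 0.413). Hsp90aa1 had 0.36, 0.20 and -0.07 in pairs 1, 2 and 3 there, and Hspa8 had 0.20, 0.26 and -0.15, with the lowest value in pair 3 as on the other platform. Serpinh1, a collagen-specific chaperone of the endoplasmic reticulum, had 0.16 ± 0.03 (SD, n = 3) and was positive in all 3 pairs. It was the 1 list member in either table that passed adjusted over the list alone (adjusted p = 0.00766 with limma), and it did not pass over all genes (adjusted p = 0.900). Chordc1, an HSP90-binding co-chaperone, had 0.08, 0.05 and 0.13, against 0.18, 0.18 and -0.10 on the first platform. Dnaja2 had 1.14 in pair 1 and 0.01 and -0.07 in the others, against 0.02, 0.11 and -0.04 on the first platform. Without pair 1 the list had a mean effect of 0.03 and no longer passed at the preset correlation (adjusted p = 0.057). Its mean was -0.2758 without the turn of swapped slides and -0.2108 with treated RNA in channel 1 alone.

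**Figure D2:**
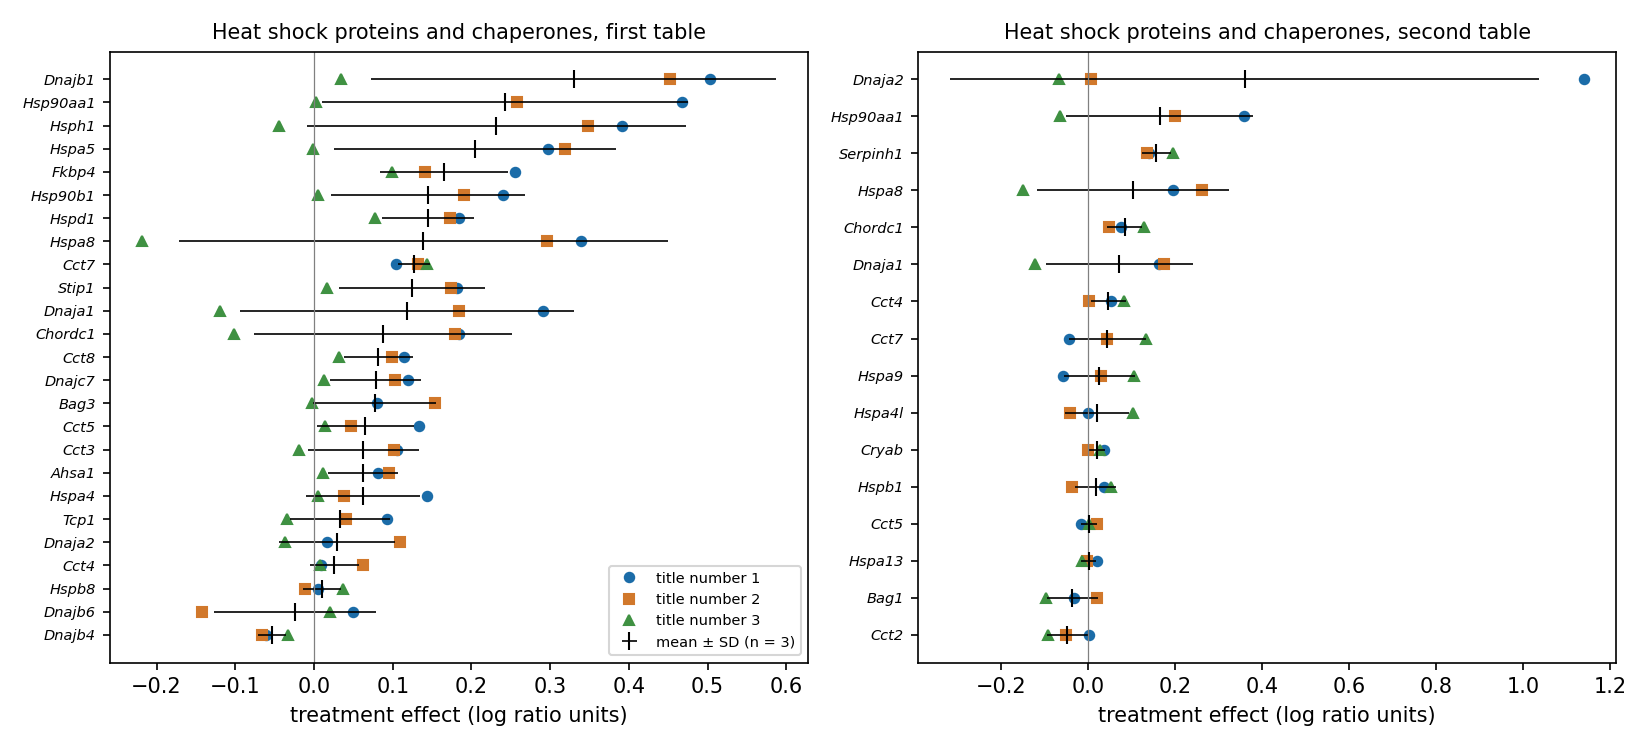
Treatment effect of each measured heat shock protein and chaperone gene (horizontal axis, log ratio units), for first table on the left and second table on the right, with 1 symbol per slide pair and the mean and SD of 3 pairs in black. In the first table Dnajb1 lies at 0.50 and 0.45 in pairs 1 and 2 and at 0.03 in pair 3.

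With swapped slides turned, genes of the ATF4 and unfolded protein response pathways, which answer amino acid shortage and misfolded protein in the endoplasmic reticulum, had positive medians in both tables, though not in every pair. Of 13 genes in the first table, 11 were positive with a median of 0.10 and pair medians of 0.07, 0.09 and 0.04 (adjusted p = 2.72e-05 at the preset correlation; adjusted p = 0.589 with an estimated correlation). Calr, a calcium-binding chaperone of the endoplasmic reticulum, had 0.19 ± 0.16 (SD, n = 3), Hspa5, its main HSP70, had 0.20 ± 0.18, and Sars, which charges serine tRNA, had 0.13 ± 0.03 and was positive in every pair, against 0.00 ± 0.08 on its second-table probe. Hspa5 also belongs to the chaperone list. On the second platform, 10 of 13 genes were positive with a median of 0.04 and pair medians of -0.02, 0.06 and 0.07 (adjusted p = 0.00171 at the preset correlation; adjusted p = 0.795 with an estimated correlation), and without pair 3 the list did not pass (adjusted p = 0.124). Xbp1, a transcription factor of the unfolded protein response, had 0.09 ± 0.06 and Pdia3, a disulfide isomerase, had 0.08 ± 0.03 there. Read without the turn, the list means were -0.2072 in the first table and -0.3256 in the second. No member passed in either table.

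Genes of G2/M and mitosis were mostly negative in the second table with swapped slides turned. This sets them apart from chaperone and ATF4 genes only under the turn: without it the list means were -0.2726 in the first table and -0.3523 in the second, on the same side as the means of those 2 lists. Among 21 genes of the second table, 4 were positive and 12 were negative in all 3 pairs, with a median of -0.05 and pair medians of -0.04, -0.05 and -0.04 (adjusted p = 1.10e-04 at the preset correlation; adjusted p = 0.413 with an estimated correlation). Top2a, the topoisomerase of dividing cells, had -0.11 ± 0.04 (SD, n = 3), Bub1, a spindle checkpoint kinase, had -0.10 ± 0.06, and Smc4, a condensin subunit, had -0.09 ± 0.06, while in the first table Top2a had -0.02 ± 0.06 and Smc4 0.02 ± 0.09. In the first table the list median was -0.01 over 25 genes, with 0.04, -0.03 and -0.07 in pairs 1, 2 and 3 (adjusted p = 0.0157 at the preset correlation; adjusted p = 0.616 with an estimated correlation), with Mki67 at -0.21 ± 0.16 and Aurkb, a mitotic kinase, at 0.14 ± 0.02, against the direction of the list. That call was lost without pair 2 (adjusted p = 0.142) and without pair 3 (adjusted p = 0.303). No member passed in either table.

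Several abundant housekeeping groups were positive in the first table, mainly through pair 1. Ribosomal protein genes had a median of 0.09 over 37 genes, with 0.18, 0.05 and 0.02 in pairs 1, 2 and 3 (adjusted p = 1.22e-12 at the preset correlation). Glycolysis genes had 0.27, 0.03 and 0.00, and all 10 were positive (adjusted p = 2.72e-05). Translation factor genes (adjusted p = 1.55e-04) and tubulins and actins (adjusted p = 0.0039) passed as well. With an estimated correlation each had an adjusted p = 0.589. Aldoc, an aldolase, had 0.19 ± 0.12 (SD, n = 3) and Rps3, a small-subunit protein, had 0.16 ± 0.11. Without pair 1, ribosomal protein genes still passed with a mean of 0.03 (adjusted p = 0.0151), while glycolysis (adjusted p = 0.227), translation factors (adjusted p = 0.0946) and tubulins and actins (adjusted p = 0.195) did not pass, and tubulins and actins did not pass without pair 2 (adjusted p = 0.0513), under quantile normalization (adjusted p = 0.0607) or after the trend on the dye component was removed (adjusted p = 0.0638), a setting chosen after seeing the data. The sign of all 4 lists depended on the turn: without it their means were -0.7171, -0.4306, -0.3548 and -0.6002 for ribosomal proteins, glycolysis, translation factors and tubulins and actins, and they were negative with treated RNA in channel 1 alone and positive with it in channel 2 alone. The means without the turn are those of the dye component itself. In the second table, with other probes, ribosomal protein genes had a median of -0.01 over 64 genes and translation factor genes -0.00 over 33, and neither passed.

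A further 3 lists passed in the first table at the preset correlation only. NRF2 targets, which answer oxidants and electrophiles, were positive for 12 of 16 genes with a median of 0.03 (adjusted p = 0.0157), led by Nfe2l2, the factor itself, at 0.19 ± 0.16 (SD, n = 3), Mt1, a metallothionein, at 0.20 ± 0.19 and Hmox1, haem oxygenase, at 0.12 ± 0.11. Their pair medians were 0.10, 0.05 and -0.005 in pairs 1, 2 and 3. Mt1 had 0.42 in pair 3, where Mt2, another metallothionein, had -0.23, with a mean of -0.01 ± 0.19. On its second-table probe Nfe2l2 had 0.04 ± 0.02. G1/S and DNA replication genes had a median of 0.06 over 22 genes (adjusted p = 0.00503), with the licensing factors Cdt1 at 0.16 ± 0.06 and Cdc6 at 0.17 ± 0.16. Proteasome genes had a median of 0.04 over 21 genes (adjusted p = 0.0157). With an estimated correlation each had an adjusted p = 0.589. Without pair 1 none of the 3 passed (adjusted p = 0.0956, 0.0592 and 0.209), nor without pair 2 (adjusted p = 0.083, 0.126 and 0.297). The proteasome call was also lost under scaling (adjusted p = 0.073), under quantile normalization (adjusted p = 0.113), with values as deposited (adjusted p = 0.0618), in the joint fit of both tables (adjusted p = 0.28) and after removal of the dye trend (adjusted p = 0.335). None of the 3 passed in the second table. Their first-table means were negative without the turn of swapped slides, at -0.2061 for NRF2 targets, -0.1708 for G1/S genes and -0.277 for proteasome genes.

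Genes that answer DNA damage showed no list shift past the threshold. The p53 target list had a median of 0.01 over 9 genes in the first table (adjusted p = 0.20) and -0.01 over 11 in the second (adjusted p = 0.849). Ccng1, a p53 target, was positive in all 3 pairs on both of its first-table probes, at 0.10 ± 0.03 and 0.14 ± 0.07 (SD, n = 3), while its second-table probe had -0.06 ± 0.22. The 2 probes of Mdm2, the p53 ubiquitin ligase, had -0.06 ± 0.18 and 0.05 ± 0.09. DNA repair genes, apoptosis regulators and immediate early genes did not pass in either table. Fos had 0.09 ± 0.24, Jun 0.06 ± 0.09, Egr1 0.03 ± 0.02 and Atf3 -0.01 ± 0.09. Of the reference genes, Gapdh had 0.07 ± 0.11, and the 10 probes of Actb lay between -0.05 and 0.06.

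Markers of cell types that whole embryos can hold did not pass either. Yolk sac visceral endoderm markers had a median of -0.02 over 11 genes in the first table (adjusted p = 0.350), neural tube markers 0.02 over 5 (adjusted p = 0.615) and trophoblast and decidua markers 0.04 over 8 (adjusted p = 0.131). Primitive erythroid markers had -0.04 over 7 genes in the second table (adjusted p = 0.351), including Hba-x, embryonic alpha-like globin, at -0.09 ± 0.05 (SD, n = 3). Cholesterol synthesis, hypoxia, oxidative phosphorylation, histone, collagen and laminin, and aldehyde dehydrogenase and glutathione transferase lists did not pass where tested. Cardiac, neural crest, somite and endothelial markers had fewer than 5 measured genes in each table and were not tested by table; in the joint fit, chosen after seeing the data, somite (adjusted p = 0.881) and endothelial markers (adjusted p = 0.957), with 5 genes each, did not pass. Among lists that did not pass, the preset test pointed up against a negative median for collagens and laminins in both tables, and in the second table for NRF2 targets, DNA repair, ribosomal protein, oxidative phosphorylation and translation factor genes. In the second table, immediate early genes and the aldehyde dehydrogenase and glutathione transferase list had a positive median and a negative mean.

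**Figure D3:**
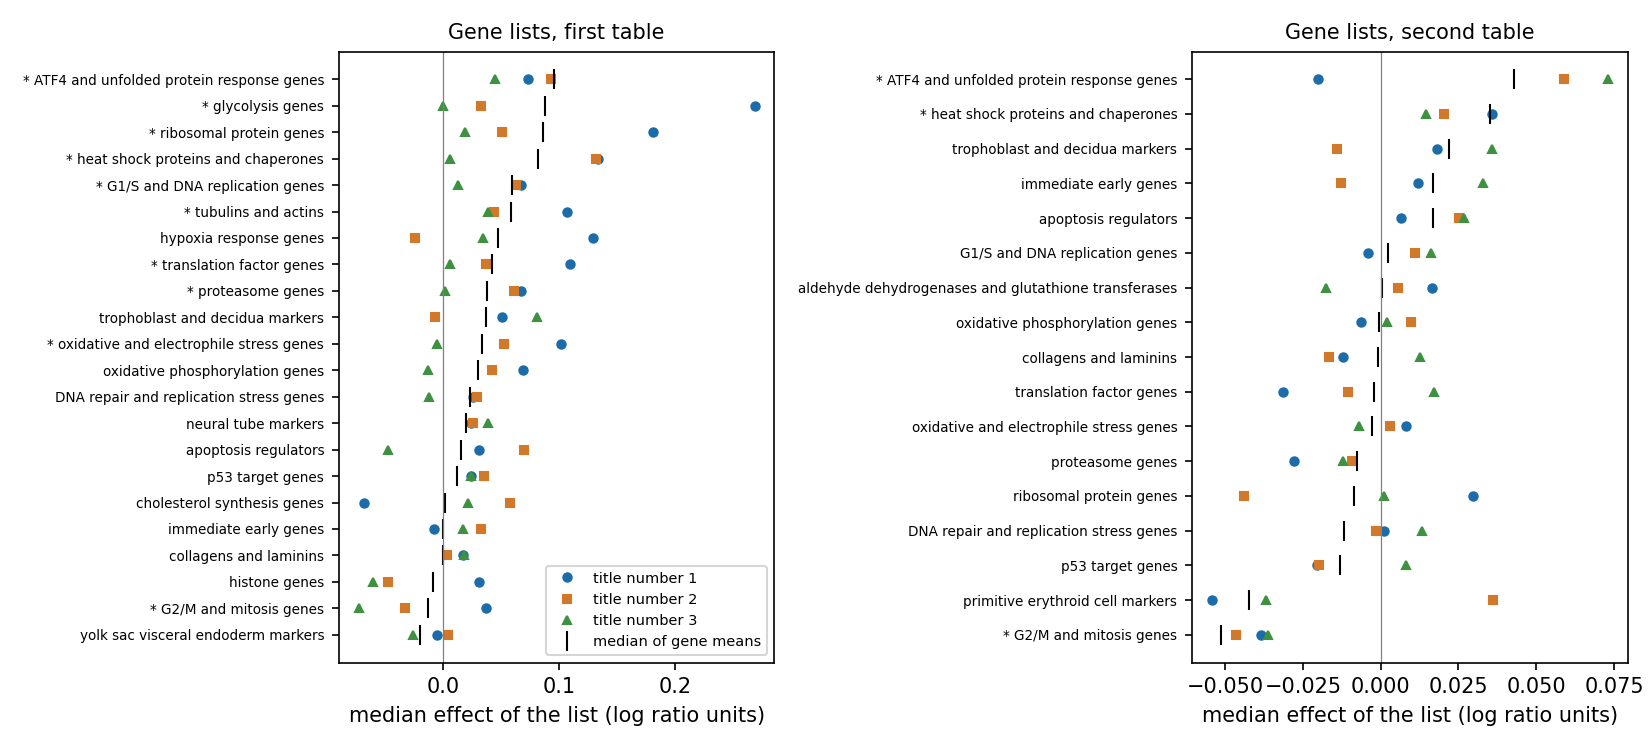
Median treatment effect of each tested gene list (horizontal axis, log ratio units; scales differ between panels) in the first table on the left and second table on the right, with 1 symbol per slide pair and a black bar for the median of the gene means. A star marks lists past the preset camera test. All of these miss the threshold with an estimated correlation, a test with few degrees of freedom at 3 pairs. Chaperones lie at 0.13 in pairs 1 and 2 and at 0.01 in pair 3 of the first table.

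The single transcripts that came closest, with the same sign in all 3 pairs, had adjusted p-values of 0.673 to 0.997 and are given as values that did not pass. Their signs hold with swapped slides turned. Of these 20, 9 changed sign without the turn, 5 with treated RNA in channel 1 alone and 8 with it in channel 2 alone. On the positive side were Serpinh1 at 0.16 ± 0.03 (SD, n = 3), Amotl2 at 0.14 ± 0.02, Jmjd6 at 0.14 ± 0.06, Spryd7 at 0.19 ± 0.03, Fkbp4 at 0.20 ± 0.08, Adarb1 at 0.12 ± 0.03, Dus1l at 0.17 ± 0.12, H19 at 0.13 ± 0.07, Nxpe2 at 0.21 ± 0.17 and Dnajb1 at 0.28 ± 0.22 on 1 of its probes. Serpinh1, Fkbp4 and Dnajb1 are chaperones or co-chaperones, Adarb1 edits RNA, and H19 is an imprinted noncoding RNA. On the negative side were Sgce at -0.18 ± 0.06, Trmt5 at -0.14 ± 0.05, Cyrib at -0.13 ± 0.02, Casd1 at -0.12 ± 0.01, Racgap1 at -0.13 ± 0.04, Gpcpd1 at -0.12 ± 0.02, Pum2 at -0.12 ± 0.03, Anapc4 at -0.12 ± 0.03, Tpd52l2 at -0.12 ± 0.02 and Nrp1 at -0.11 ± 0.02. Racgap1 acts in cytokinesis and Anapc4 is a subunit of the anaphase-promoting complex. An effect of 0.3 would be a 1.23-fold difference in base 2 and a 1.35-fold difference in base e.

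With swapped slides turned, slide pairs shared little of their treatment effects. If the values had been deposited as treated over control, the names treatment effect and dye component would change places in this paragraph. Across probes, which are not independent replicates, Pearson's r between pairs of a table ran from -0.144 to 0.009 in the first table and from -0.051 to 0.15 in the second. Within a pair, the first and second arrays gave treatment effects with r from 0.305 to 0.598 in the first table and from 0.037 to 0.273 in the second. Under this turned reading the dye component was larger, with an SD across probes of 0.271 to 0.679 in the first table, against 0.0987 to 0.124 for the treatment effect, and of 0.241 to 0.566 against 0.058 to 0.0866 in the second. It correlated between pairs with r from 0.158 to 0.747 and from 0.099 to 0.875. Ribosomal protein genes had a median dye component of -0.783 in the first table and -0.862 in the second. Tested like the treatment effect, the dye component passed for 219 probes in the first table, all negative, and for 0 in the second, where 1254 had an unadjusted p under 0.05 with limma. Within pairs 1, 2 and 3 of the first table, treatment effect and dye component correlated with r = -0.456, 0.374 and 0.154, and within those of the second with r = 0.104, 0.118 and 0.143.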

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

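Removal of the dye trend, centring of runs of 240 probe numbers and the joint fit of both tables were chosen after seeing the data. The count of 0 probes in each table held under scaling, quantile normalization, robust eBayes, an adjusted p limit of 0.10, the fit on single arrays and the 3 added settings; the joint fit had 271 of 6971 genes with an unadjusted p under 0.05 in limma. Limits of 0.01 or 1.5-fold can only give 0 here, as can the exact sign-flip permutation test (smallest possible p = 0.25). Values as deposited gave 33 probes in the first table and 1 in the second, and turned the dye component from 219 probes to 0 in the first table and from 0 to 6880 in the second, since a shift of whole arrays then counts as an effect. Of first-table probes, 219 passed without the turn, 174 in slides with treated RNA in channel 1 alone and 668 in those with it in channel 2 alone, settings that keep the dye effect if every value is channel 1 over channel 2; in the second table these gave 0. Leaving out 1 pair gave 24 to 30 probes in the first table (24 without pair 1, 30 without pair 2, 24 without pair 3) and 0 to 58 in the second (40 without pair 1, 58 without pair 2, 0 without pair 3); the cause was not tested.

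Lists past the preset test numbered 10 in the first table and 3 in the second, and 0 in each with an estimated correlation or with fry. Leaving out a pair gave 4 to 9 lists in the first table (4 without pair 1) and 2 to 4 in the second. The second table gave 6 lists without the turn, 5 and 9 in slides with treated RNA in channel 1 or channel 2 alone, and 9 in the joint fit, which tests 26 lists over more genes. Every positive list that had passed reversed without the turn and with treated RNA in channel 1 alone. Without the turn the list means in the first table were -0.2061 for NRF2 targets, -0.3145 for chaperones, -0.2072 for ATF4 and unfolded protein response genes, -0.1708 for G1/S, -0.4306 for glycolysis, -0.7171 for ribosomal proteins, -0.277 for proteasome, -0.3548 for translation factors and -0.6002 for tubulins and actins, and in the second -0.2758 for chaperones and -0.3256 for ATF4 genes. With treated RNA in channel 1 alone they were, in the same order, -0.1576, -0.2117, -0.121, -0.1281, -0.3352, -0.6378, -0.2432, -0.311 and -0.5444, and -0.2108 and -0.2881. G2/M genes kept their sign in these 2 settings (-0.2726 and -0.3523 without the turn), on the same side as chaperone and ATF4 genes. With treated RNA in channel 2 alone, G2/M genes reversed to 0.2457 and 0.3076. Of 20 transcripts named for the smallest p, 0 turned sign under scaling, quantile normalization or values as deposited, but 9 did without the turn, 5 with treated RNA in channel 1 alone and 8 with it in channel 2 alone. Of all 161 named values, 57 turned sign as deposited. As deposited, the means of all 9 positive first-table lists were negative (chaperones -0.02106, ribosomal proteins -0.04457), as was that of ATF4 genes in the second (-0.01537), while the preset test, which compares with other genes, kept its direction.

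Some planned settings were not run. Title numbers gave 1 pair per number in each table, and each table holds a single value of the other title number, so blocks, averages and the comparison by title number had no values. No further pairing of the groups was possible because each array already holds both, so every value is itself a paired comparison. No value was missing and the values are log ratios, so filters on measured pairs and a pseudocount did not apply. The tables hold different slide pairs, so binding them was done only as the joint fit. Signal over background is unknown.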

Other observations

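Apart from the sign flips, all tests of explanations reported here were chosen after the list results were seen, including the removal of the dye trend; for the 2 tests of that trend on whole patterns the limits were written before the medians without the trend were seen. Treatment effects of the 943 genes on both tables correlated with r = 0.11, 0.066 and 0.129 between pairs that share number 1, 2 or 3, and with r from -0.033 to 0.055 between others. With 6 possible matchings no test of this can pass, and the labels do not say what the numbers mark.

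In the first table the chaperone list had medians of 0.133, 0.132 and 0.00555 in pairs 1, 2 and 3. In the second they were 0.0357, 0.0204 and 0.0146, where the median of pair 3 is not set apart. Hsp90aa1 and Hspa8 were lowest in pair 3 of the second table too, and Serpinh1 and Chordc1 highest. In the first table, however, Chordc1 was lowest in pair 3, at -0.10. An incomplete cancelling of the dye effect was tested by removing the trend of each pair's effect on its dye component: the share of the list median kept was 42% in pair 1 and 84.6% in pair 2 of the first table, and 92.7% and 104% in the second. The limit, 50% of the median in all 4 pairs and a place above random lists, was not met, so this stays open. In pair 1 of the first table the median of 0.0561 left after removal was still above 99.33% of random lists. Pair 2 of the first table and pair 1 of the second met the limit, but this cannot exclude an incomplete cancelling. In pair 2 of the first table the median dye component of the list was -0.00101, where the trend could take away little. In pair 1 of the second, treatment effect and dye component correlated with only r = 0.104. Removal of a smooth trend also leaves dye effects of single probes that did not cancel. Pair 2 of the second table lay within the range of random lists. Over all 3 pairs the first-table list kept a mean of 0.08428 of 0.1028 and passed the preset test (adjusted p = 9.12e-09), a test that the measured list passed too while missing the threshold with an estimated correlation (adjusted p = 0.589) and with fry (adjusted p = 0.446). An exchange of treated and control RNA in pair 3 of the first table would give a median of -0.132. The measured median was 0.00555 (bootstrap 95% interval -0.0185 to 0.0171), and 0.0294 after removal of the dye trend. This interval resamples genes within 1 slide pair, whose estimated correlation in the list was 0.394, and measures no spread between pairs. Hspa8 and Dnaja1 were negative in pair 3 of both tables, at -0.22 and -0.12 in the first, while Dnajb1 had 0.03 there. An exchange is therefore not decided by the first table, nor by the second, with 0.0146 (-0.0663 to 0.103). A difference between cultures in the response to 4CP may remain, and was not tested because the labels define no such group.

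Ribosomal protein and glycolysis lists were positive in pair 1 of the first table. After removal of the dye trend, ribosomal protein genes kept 10.2% of their median there, as an incomplete cancelling of the dye effect would give, while their medians were then 0.0748 and 0.071 in pairs 2 and 3. Over all 3 pairs their list then had a mean of 0.0552 and still passed camera at the preset correlation (adjusted p = 4.97e-10). Glycolysis (adjusted p = 3.75e-05) and translation factor genes (adjusted p = 0.0047) still passed that test as well. Glycolysis genes kept 66.5%, which argues against the dye trend as the whole cause for them. No biological explanation was tested.

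The 219 probes found without the turn could reflect the dye, or a treatment effect if the values had been deposited as treated over control. In the second case the turned values would hold the dye effect and should repeat between pairs, but the highest r between pairs of a table was 0.15. The component without the turn repeated more, with r from 0.158 to 0.747 in the first table and from 0.099 to 0.875 in the second, as a dye effect would. These correlations do not decide, since the normalization before deposit is not stated and a repeating dye effect could have been removed by it. Medians of the arrays as deposited kept their sign across the swap in every pair except pair 2 of the first table. In pair 3 of the second table they were 2.08 and 1.87 with treated RNA in channel 1, and 2.10 and 1.85 with it in channel 2. In pair 3 of the first they were 0.73 and 0.58, and 1.12 and 0.98. A channel offset would change sign if swapped slides had been turned, so these medians argue against that reading for those pairs. An offset that follows the treated RNA would keep its sign too and was not tested.

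With 3 pairs there are 4 sign flips, too few to exclude chance. All 4 gave 0 probes in each table, so the real count was 0 and the highest of the others 0. Unadjusted p-values under 0.05 numbered 180 as measured against 434, 513 and 246 with pair 1, 2 or 3 flipped in the first table, where the real signs gave the fewest, and 401 against 196, 107 and 362 in the second.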
